A study of Mus musculus with 2 samples.

How the data were processed

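The series has 2 single-cell RNA libraries, 1 per genotype, from intracranial SB28 tumours; subcutaneous tumours named in the design text were not analysed here. Per the labels' protocols, tumours were dissociated enzymatically and mechanically, and libraries were made with the Chromium NextGEM Single Cell 3' kit v3.1. Per the submitters' processing notes, Cell Ranger 3.0.2, Seurat 4.0.6 and the mm10 genome were used; the role and order of these tools, the settings, the annotation release and the way the libraries were joined are not given in the sources used here.

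The 2 deposited lists hold identifiers and no measured values. The first gives each cell as a 16-base barcode followed by a library number, 1 or 2. The second gives each feature's identifier, symbol and type, and every type is gene expression. Their names describe them as parts of a filtered feature-barcode matrix; the UMI counts of that matrix were not used here. Filters on cells, doublets, clustering, cell types, shares of cells and expression were therefore not examined. The design fixed before the data were examined had included cell class shares and expression per class, to be run only with counts.

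Samples were grouped by the genotype in their labels. The number after the barcode matches no label, and library order was not used to assign one, so no comparison between genotypes was made. Barcodes were counted per library number, with exact Clopper-Pearson 95% intervals that cover counting error only. Barcode sequences in both libraries were counted by exact match. Their number was set against the hypergeometric distribution for independent, even draws from the kit's list of 6794880 sequences, a list size that is general knowledge of the kit and not a value in the deposited lists. The calculation was tested on 200 simulated pairs of draws. A comparison with shifted barcode sequences, also foreseen in the design, was not run.

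Feature identifiers were matched without version numbers to the GENCODE M21 annotation, which is on GRCm38, the assembly named mm10. Coordinates, biotypes and transcripts are from M21. Fixed genes were matched by symbol, and Sting1 also by its older symbol, Tmem173, as written in the design. The feature list is of another release: 93 of its Ensembl identifiers were absent from M21, 56 M21 genes were absent from it, and 813 symbols differed. Genes named in the text are those of the pathway and marker lists written before the data were examined, plus partners found for them; the ribosomal protein genes and the genes that entered or left under another setting were named after their values were seen. The pathway lists were the target, other PP2A subunits, the Cre driver, the STING pathway, the type I interferon response, antigen presentation, suppressive myeloid genes and effector T and NK genes. The marker lists were tumour, microglia, monocyte or macrophage, neutrophil, dendritic, T, NK, B, endothelial, pericyte or fibroblast, astrocyte, oligodendrocyte and erythrocyte genes and dissociation stress genes.

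The search for sequence in common was designed after the lists had been seen. The longest coding transcript with a complete 3' end was taken for each listed protein-coding gene. Its 3' end was compared with all M21 transcripts of other listed genes on the same strand. The search used blastn 2.17.0 (megablast, word size 20, low-complexity seeds masked), and sharing was judged over the last 500 bases. Sequence repeated across the genome was not masked, so a repeat within an end could count as sharing. A gene counted as sharing when a stretch of at least 95% identity over its whole aligned length covered at least 90 of those 500 bases. A read of such a stretch need not be ambiguous, because a few mismatches can place it. The stretch could extend upstream of those 500 bases, and identity within them was not computed separately. A diverged end could therefore be counted through a closer upstream part. A close end inside a longer alignment below 95% could be missed. The longest transcript may also not be the one expressed, and sequence at unannotated places in the genome was not searched. On planted copies, 100 of 100 with 2% of bases substituted were found, and 0 of 100 with 12% substituted, among 21749 genes searched. The copies were 500 bases long, and none was near the 95% limit or as short as 90 bases. They therefore say little about such borderline cases. Lists of at least 6 pathway genes and the joined markers were compared with all other protein-coding genes by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment. Statistics used SciPy 1.17.1.

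Alternatives for the barcodes and the matching of symbols were fixed before the data were examined. Those for the sequence search were added later: windows of 300 and 1000 bases, 98% identity, stretches of 60 bases, partners limited to protein-coding, lincRNA, antisense, immunoglobulin and T cell receptor genes (the pseudogenes of the last 2 classes included), and partners that do not overlap the gene.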

Results

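The data came from SB28 tumours, a mouse glioma line, grown in the brain of C57BL/6 mice and collected 18 days after implantation. 1 tumour library came from a wild-type host (WT) and 1 from a host labelled PP2AcKO, in which, by the series' design text, LysM-driven Cre removes the catalytic subunit of protein phosphatase 2A. LysM is the product of Lyz2, a lysozyme gene of myeloid cells. The question set by the title of the series is whether loss of this subunit changes STING and type I interferon signalling in glioblastoma. Cell suspensions were profiled with droplet 3' single-cell RNA sequencing. The analysis covered the list of called cell barcodes and the list of features against which reads were counted. UMI counts were not analysed here, so no gene has an expression value and no cell type was assigned. Depth per cell is not known here.

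The barcode list held 17379 cells. Library number 1 had 7714 of them, or 44.4% (exact Clopper-Pearson 95% interval 43.6 to 45.1), and library number 2 had 9665, or 55.6% (54.9 to 56.4). The intervals cover counting error only. No label tied either library number to a genotype, so this difference was not read as one between WT and PP2AcKO tumours. With 1 library per genotype, it would also have had no replicate check. The libraries had 19 of the 16-base barcode sequences in common, 0.246% of library 1 and 0.197% of library 2. Independent draws from the kit's barcode list would share 11.0 on average, and the exact Poisson 95% interval of the observed number ran from 11.4 to 29.7. The one-sided exact hypergeometric test gave p = 0.017.

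The feature list held 55575 entries, of which 55573 were Ensembl mouse genes. The other 2 were the reporter sequences sfGFP and eGFP, forms of green fluorescent protein, on the last lines of the list. No entry was a Cre recombinase or a luciferase. Of the Ensembl genes, 55480 were found in the GENCODE M21 annotation of the same mouse assembly (mm10, GRCm38). Among these, 21980 were protein-coding (39.6%), 13525 were pseudogenes of any class (24.4%), 5849 were lincRNAs and 2207 were microRNAs. The list therefore covered a full annotation, pseudogenes included. Repeated symbols were few, with 117 symbols standing on more than 1 line.

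The gene targeted in the PP2AcKO host, Ppp2ca (ENSMUSG00000020349), was listed. It encodes the alpha form of the PP2A catalytic subunit and lies on the plus strand of chromosome 11, from 52098681 to 52127778. Its longest complete coding transcript has 7 exons and 7102 bases, of which 5804 are 3' UTR. The last 500 bases, where 3' sequencing would read this transcript, lie wholly in the 3' UTR. They had no counted stretch in common with another listed gene, including Ppp2cb on chromosome 8, which encodes the beta form. Only the end of this longest transcript was searched, so any other 3' end of Ppp2ca was not covered. The gene body overlapped 4 other listed genes, 1 of them on the same strand. Which part of Ppp2ca the Cre removes is not given in the sources used here, so whether a 3' count would report the deletion is open.

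All 120 genes of the 22 fixed lists were found among the features. Sting1, which encodes the STING adaptor, stood in the feature list under its older symbol, Tmem173, and lies on chromosome 18 from 35733679 to 35740554. The STING list was complete, with Cgas, which makes the cyclic dinucleotide that activates STING, and with the kinase gene Tbk1 and the transcription factor gene Irf3. The type I interferon list was complete at 18 genes, among them Ifnb1 and the receptor gene Ifnar1. All 13 antigen presentation genes were listed, as were all 63 marker genes.

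Whether the 3' ends of these genes had sequence in common with other listed genes was then examined; no reads or counts entered this search. The ends were searched for 119 of the 120 genes, each over 500 bases except S100a8, whose transcript of 486 bases was used whole. Of these genes, 10 had at least 90 such bases in a stretch of 95% identity or more in another listed gene (8.40%, exact 95% interval 4.10 to 14.9). Over all 21749 protein-coding genes searched, 2847 did (13.1%). At 98% identity or more, 4 of the fixed genes and 1953 of all protein-coding genes did. No list of at least 6 pathway genes, nor the joined markers, differed from the other protein-coding genes (two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 1 for each of 7 tests, at 95% identity). These lists are short. For the interferon list, with 3 of 18 genes (16.7%), the exact interval ran from 3.58 to 41.4%.

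Several of the 10 genes belong to the pathways named in the title of the series. In what follows, bases in common are those inside stretches of at least 95% identity over their whole aligned length, and they need not be identical. Isg15, an interferon-induced ubiquitin-like modifier on chromosome 4 (156199424 to 156200818), had 338 of its last 500 bases in common with the processed pseudogene Gm9706 on chromosome 17. The interferon-induced gene Ifit3 had all 500 in common with its neighbour Ifit3b on chromosome 19. Oas1a, an oligoadenylate synthetase gene, had 500 in common with Oas1g on chromosome 5. Trex1, the exonuclease gene that limits cytosolic DNA, lies on the same strand as Atrip and inside it on chromosome 9 (109057933 to 109059734), and its last 500 bases all belong to Atrip transcripts too. Of the antigen presentation genes, H2-D1 had 150 bases in common with parts of 4 unrelated genes, including Cflar. H2-K1, B2m, Tap1 and the other genes of that list had none in a counted stretch. Close parts inside longer alignments below 95% were not counted. With the limit at 98%, Oas1a and Trex1 still had 500 bases in common. No counted stretch of Isg15, Ifit3 or H2-D1 reached that limit over its whole length, and shorter parts at 98% were not searched for.

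Among the genes that mark cell types or the Cre driver, Lyz2 had 496 of 500 bases in common with Lyz1, the other mouse lysozyme gene, and both lie on chromosome 10. The monocyte marker Ly6c2 had 500 in common with Ly6c1 on chromosome 15. The red blood cell marker Hba-a1 had 500 in common with its duplicate Hba-a2 on chromosome 11. Mki67, a proliferation marker, had 190 in common with the processed pseudogene Gm44521. The neutrophil marker Csf3r had 153 in common with 62 other genes, among them Slc6a20b on chromosome 9 and Med16 on chromosome 10. Whether the Csf3r stretch is a repeat was not examined. With the limit at 98%, Hba-a1 still had 500 and Mki67 190, and no counted stretch of Lyz2, Ly6c2 or Csf3r reached it over its whole length. The microglia markers, among them P2ry12, Tmem119 and Sall1, had no such stretch, and neither did the T cell markers searched, such as Cd3e and Cd8a. Trac, the T cell receptor constant gene, was not searched because it is not annotated as protein-coding.

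**Figure D1:**
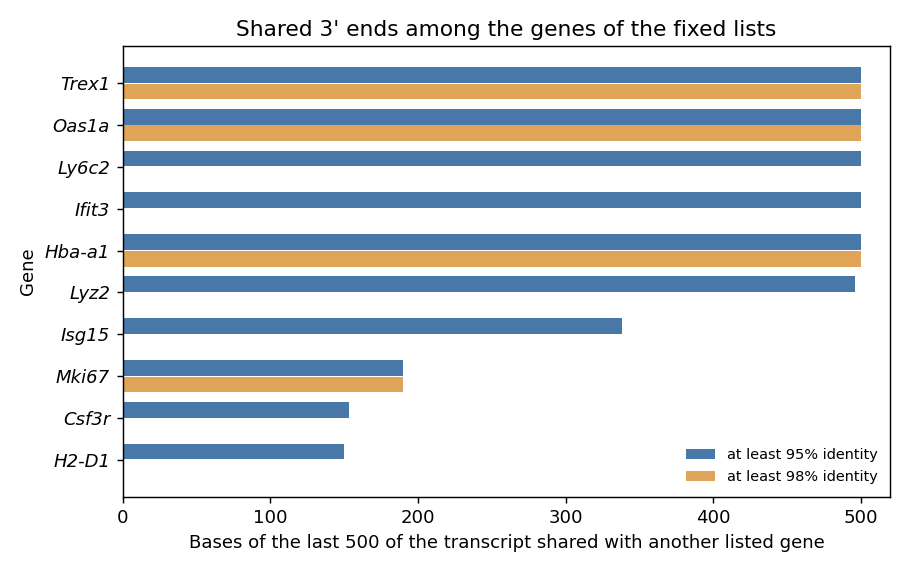
Bases of the last 500 of each transcript (horizontal axis, from 0) inside a stretch in common with other listed genes, pooled over those genes. Shown are the 10 genes of the fixed lists with such a stretch. Blue bars count stretches of at least 95% identity over their whole aligned length and orange bars those of at least 98%. At 98% the bars remain for Trex1, Oas1a and Hba-a1 at 500 bases and for Mki67 at 190. A missing orange bar means that no counted stretch reached 98% over its whole length, and shorter parts were not searched for.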

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

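The alternatives to the sequence search were chosen after seeing the data; those for barcodes and symbols were not. Leaving out barcodes found in both libraries gave 7695 and 9646 cells, and leaving out barcodes with a neighbour 1 base away gave 7712 and 9665; no barcode had a run of 6 identical bases. Allowing 1 mismatch left 19 shared sequences. Taking every 16-base sequence of the observed composition as possible, rather than the kit's list, lowered the expected number from 11.0 to 0.018, since that construction ignores the list. Matching symbols without regard to case, or by identifier, found 120 of the 120 fixed genes. At 98% identity the number of fixed genes with a shared 3' end fell from 10 to 4, by construction of the stricter limit: Trex1, Oas1a, Hba-a1 and Mki67 stayed, and Isg15, Ifit3, Lyz2, Ly6c2, H2-D1 and Csf3r left. The limit applies to a whole aligned stretch, so the genes that left may still hold shorter parts at 98%. A window of 1000 bases raised it to 15, adding Cgas, Ifng, Cd79a, Hspa1a and Hspa1b. Stretches of 60 bases gave 11, adding Ifnar1. A window of 300 bases gave 9, without Mki67, and leaving out overlapping partners gave 9, without Trex1. Limiting the partners' biotypes gave 8, without Isg15 and Mki67. The number over all protein-coding genes ranged from 1953 to 3628 around 2847. The 3 other settings foreseen for cell classes and expression were not run, because UMI counts were not used here. The missing depth per cell limits every statement to identifiers and sequence.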

Other observations

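Ribosomal protein genes shared 3' ends more often than the other protein-coding genes. Of 82 such genes searched, 60 (73.2%) had a stretch in common with another listed gene, against 2787 of the 21667 others (12.9%; two-sided Fisher's exact test, p = 1.57e-35). With partners limited to the biotypes that the kit maker's filtered references usually keep, 17 did (20.7%), against 2465 of the others (11.4%; the same exact test, p = 0.013). The family and these 2 tests were chosen after the counts were seen, and genes are not independent replicates.

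The comparison of shared barcodes with the kit's list was fixed before the data were examined. The limits for judging that comparison and the tests of its explanations were set after the number was seen. The comparison with shifted sequences, fixed with it, was not run. For 3' ends, the 2 hypotheses that follow were written before their results. The 19 barcode sequences found in both libraries exceeded the 11.0 expected. Even draws from the kit's list give 19 or more with a probability of 0.017, which argues against chance alone, though this was 1 uncorrected test and the list size was taken from outside the data. Uneven base composition is a candidate explanation: position 1 was T in 28.6% and 28.0% of barcodes. Scaling by the composition at single positions raised the expectation only from 11.0 to 11.3, just under the interval's lower end of 11.4. The limit written for this explanation counts that against it, but the margin is too small to decide. The scaling also measured composition against even base shares, not against the kit's list, whose composition was not examined. An excess of T already present in the list would not raise the expected number. The test therefore cannot decide on single-position composition. Unevenness in combinations of bases was not tested and stays open. Reads carried over between the libraries may also have contributed to the 19, and this cannot be told apart from uneven bead use without UMI totals. No biological explanation was tested.

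A hypothesis was that most shared 3' ends arise because the full annotation lists biotypes left out of filtered references, among them pseudogenes other than those of immunoglobulins and T cell receptors. It failed for protein-coding genes as a whole: only 12.8% of the 2847 sharing genes (exact 95% interval 11.6 to 14.1) had no partner of the filtered biotypes. Isg15 and Mki67 were the fixed genes of that kind. For them, and for many ribosomal protein genes, counts on these features may differ from counts on a filtered reference, where the number of fixed genes with a partner was 8 in place of 10. Whether counts differ was not tested.

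A further hypothesis was that interferon and antigen presentation genes, as members of recently duplicated families, share 3' ends more often than other protein-coding genes. In these lists 4 of 31 did (12.9%, exact 95% interval 3.63 to 29.8), and Fisher's exact test gave p = 1 with an odds ratio of 0.98. The interval is too wide to exclude a difference in either direction. The count also takes any shared stretch: Isg15 matched a processed pseudogene and H2-D1 matched unrelated genes. The test therefore cannot single out duplication within families.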
